A study of Mus musculus with 2 samples.

How the data were processed

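Total RNA from 1 pancreatic cancer and 1 normal pancreas, each from a male mouse aged 7 weeks, was measured on miRCURY LNA microRNA arrays, which carry capture probes for microRNAs (miRNAs, short RNAs that lower the output of messenger RNAs) built with locked nucleic acid. Each array had 2 colours. Per the labels' protocols, the tissue RNA carried Hy3 (the green channel) and a reference blended in equal parts from the samples carried Hy5 (the red channel), so a positive log ratio means more signal in the tissue than in the reference. The design has 1 array per group. Array, slide and group therefore cannot be told apart, and no p-value, standard error across animals or count of significant miRNAs was computed.

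The deposited scanner files hold, per the file headers, the median intensity of each spot and of its local background in both channels, a background-subtracted intensity, a dye-normalized processed intensity and quality flags, all read with Agilent Feature Extraction 10.7.3.1. The log10 ratio column of the same files, per the file headers, is red over green processed signal, and it was not used for the values reported. The deposited value table holds a linear ratio per probe. For all 2658 probe IDs on both arrays that ratio equalled, within 0.1%, the mean over a probe's spots of processed Hy3 over processed Hy5. It is thus on a linear scale, tissue over reference, with no further centring, and its column medians were 1.03 for both arrays.

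The design fixed before the data were examined called for mean foreground signals, but the files give medians, which were used instead. It also called for mouse-named probes, 18 lists with 185 miRNA entries and a rule naming the 13 highest and the 13 lowest probes. The files name probes by number only. The systematic name column was empty, no probe ID occurred among the symbols, synonyms, locus tags or accessions of the mouse gene table used here, and 0 of the list entries could be matched. No list was therefore tested, no miRNA is named and no random lists were drawn. All probes with an ID were analysed whatever their species, and only the 2 highest and the 2 lowest probe IDs are printed.

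Each array had 11204 spots. Of the 2658 IDs, 2648 were spotted 4 times and 5 were spotted 8 times, and these 2653 were analysed. The other 5 IDs, spotted 70 to 180 times, were read as control features after the data were seen, since the control column held 0 for every spot. They were left out with 104 spots that shared the placeholder ID -1. Spots with an outlier flag in either channel numbered 51 on the tumour array and 71 on the normal array. They entered background correction and normalization and were left out when log ratios were averaged. The brightness values include them.

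Background was corrected with normexp (offset 50) on the median signals, and log ratios were normalized within each array by loess (span 0.3) with the left-out features at weight 0, in limma 3.58.1 under R 4.3.3. Log2(Hy3/Hy5) was averaged over the spots of a probe. The value reported is the tumour array's mean minus the normal array's mean, and the SD given is that between spots of one array, which is technical error only. A probe passed the scanner flag when more than 50% of its kept spots were marked well above background in Hy3. The rule of size counted probes that passed on both arrays, with a difference of at least 1 on the log2 scale (2-fold) and with all kept spots of one array beyond all kept spots of the other. As a stricter level, chosen after the data were seen, a probe's mean Hy3 brightness was set against the brightest Hy3 spot of 4 dim control features on the same array. Probes that passed the flag on 1 array only did not reach it. The design planned a bound for them, from Hy3 after loess and Aquantile. It set their level against the other array's lowest flagged level, or their own level there if higher. The offset of 50 pulls the differences of dim probes towards 0, so their folds are understated. The number of arrays, not the number of spots, limits the precision.

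The steps were tested on simulated arrays for the comparison of tumour with normal pancreas, with an equal blend as the reference. With 2653 probes, of which 200 bright ones changed evenly in both directions, the rule of size after loess recovered 98.0% of differences of 1.5 and 100% of differences of 3 on the log2 scale and called 0% of unchanged probes. With the same number changed in one direction, it recovered 9% of differences of 1.5 and 97% of differences of 3, and called 2.53% of unchanged probes. Without normalization the values for one-sided change were 98%, 100% and 0%. Both simulated arrays had the same channel gains and no dye bias that differed between them, so skipping normalization carried no penalty there. The simulation therefore does not show which setting is nearer the truth on the real arrays. Other background corrections, normalizations, single-channel values, the deposited table, spot medians, filters and thresholds were planned as alternatives. The equal-blend anchor, the filter on mean level, the level of the dim control features and equal loess weights were added after the data were seen. Under an alternative, counts and the SD of the reference difference were called moved beyond 1.5 times, median differences beyond the median spot SD of a difference (0.13) and correlations beyond 0.1.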

Results

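MicroRNA levels were measured in a pancreatic cancer of a mouse that carries an activated Kras allele and lacks the TGF-beta receptor gene Tgfbr2 in the pancreas, and in normal pancreas of a control mouse. Kras encodes a small GTPase that drives growth signalling, and Tgfbr2 encodes a receptor of the growth-restraining TGF-beta pathway. Neither gene is measured by a miRNA array, so the genotype cannot be checked from these data. There was 1 array per tissue (n = 1 each), and each tissue was read against the same blended reference. The median spot brightness in Hy3, which carried the tissue RNA, was 107 on the tumour array and 102 on the normal array, over a local background of 24 on both. The 90th percentile of Hy3 brightness was 564 for the tumour and 289 for normal pancreas. In Hy5, which carried the reference, it was 462 on the tumour array and 587 on the normal array. The scanner flag put 96.4% of tumour spots and 97.4% of normal spots well above background in Hy3, so it separated few probes. In Hy5 the flag was met by 66.5% and 55.9% of spots. No Hy3 spot was saturated, and 1 Hy5 spot on the tumour array and 14 on the normal array were.

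The comparison of the tumour with normal pancreas asked which miRNA probes differ between the tissues. Of 2516 probes that passed the scanner flag in both tissues, 168 were at least 2-fold higher in the tumour and 72 were at least 2-fold lower, while 2276 did not meet this rule. At least 4-fold differences were found for 43 probes higher and 25 probes lower in the tumour, and at least 16-fold differences for 5 and 3. Without within-array normalization these counts were 141 and 7 at 4-fold and 14 and 0 at 16-fold. The higher probes made up 70.0% of those that met the 2-fold rule. At 2-fold that setting gave 371 higher and 18 lower probes, so that 95.4% were higher. It moved the median difference of all probes from -0.03 to 0.15, a shift of 0.18 on the log2 scale. Of the 168 higher probes 167 were also at least 2-fold higher without normalization. Of the 72 lower probes 18 were also at least 2-fold lower, and the other 54 differed by less than 2-fold. No probe met the rule in opposite directions under the 2 settings. The flag is a low bar, since 1841 of the 2516 probes did not exceed in either tissue the brightest Hy3 spot of 4 dim repeated features (165 on the tumour array and 186 on the normal array). Of the 168 higher probes 59 exceeded this level in both tissues, 104 in the tumour only and 5 in neither. Of the 72 lower probes 64 exceeded it in both tissues, 6 in normal pancreas only and 2 in neither. Without normalization 149 of the 371 higher and 14 of the 18 lower probes exceeded it in both tissues. The difference of a probe that did not exceed it in both tissues has no exact size. These counts describe 1 tumour and 1 normal pancreas, and no replicate check of any difference was possible.

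**Figure D1:**
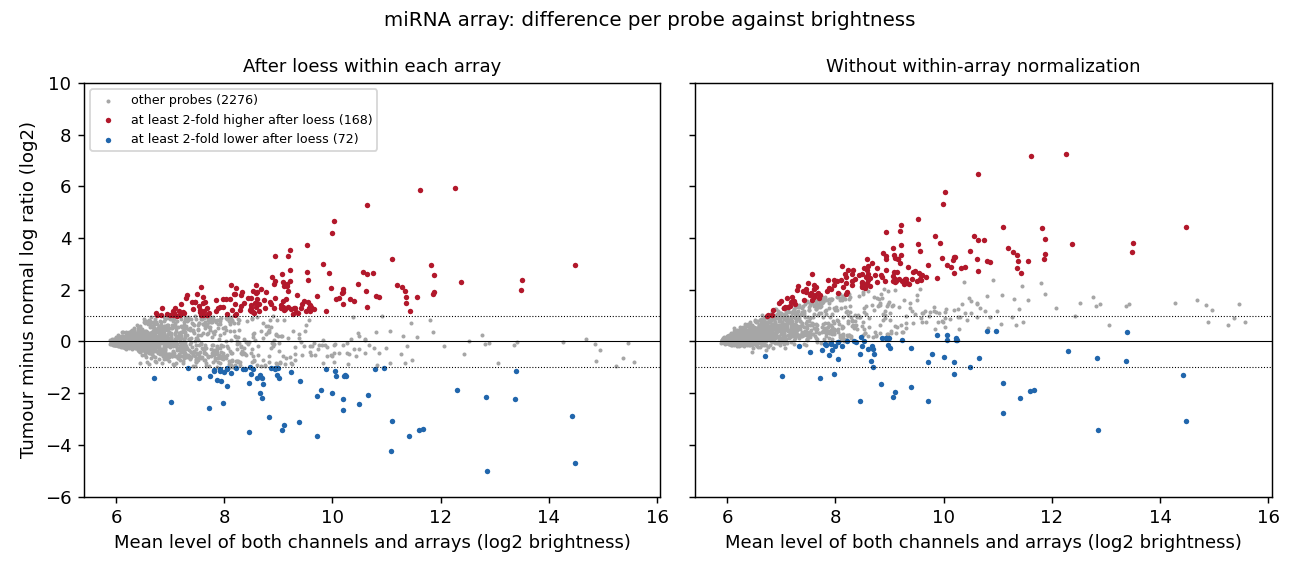
Difference in log2(Hy3/Hy5) between the tumour and the normal array for each of 2516 probes (vertical axis, log2) against its mean level over both channels and arrays (horizontal axis, log2 brightness), after loess and without within-array normalization. Each point is 1 probe, coloured by its class after loess (168 higher, 72 lower, 2276 others), and dotted lines mark 2-fold differences. Bright probes lie higher in the right panel, where the split was 371 higher to 18 lower.

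The probes that differed were mostly bright ones. Among 395 probes with a mean level of at least 8 on the log2 scale, 126 (31.9%) were at least 2-fold higher in the tumour, 58 (14.7%) were at least 2-fold lower and 211 met neither rule. Among the 2121 dimmer probes, 42 were higher and 14 were lower, or 2.64% in all. The median difference of the bright probes was 0.07 after loess and 1.29 without normalization, where 235 of them were at least 2-fold higher and 15 at least 2-fold lower.

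The probes with the largest measured excess in the tumour were probes 5740 and 147506. For probe 5740 the log ratio to the reference was 0.38 ± 0.03 in the tumour and -5.57 ± 0.06 in normal pancreas (SD over 4 spots), a difference of 5.95. Its spots had a mean Hy3 brightness of 18762 in the tumour and 144 in normal pancreas. Probe 147506 had 0.33 ± 0.02 against -5.54 ± 0.12, a difference of 5.87, and a Hy3 brightness of 9557 against 126.0. Both normal levels lay below the 186 of the dim repeated features, so the differences of these probes have no exact size or order. The probe with the largest deficit in the tumour was probe 146198, at -3.20 ± 0.02 in the tumour and 1.80 ± 0.02 in normal pancreas. The difference was -5.01, or 32.1-fold higher in normal pancreas, with a Hy3 brightness of 1330 in the tumour and 15860 in the normal tissue. Probe 147629 had a difference of -4.70, from -2.83 ± 0.02 in the tumour to 1.87 ± 0.05 in normal pancreas, with a Hy3 brightness of 4540 against 49464. Without normalization the 4 differences were 7.25, 7.18, -3.42 and -3.08, so that the folds of all 4 probes moved by more than 1.5 times and those of the probes lower in the tumour were smaller. The files do not pair these probe IDs with miRNAs.

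**Figure D2:**
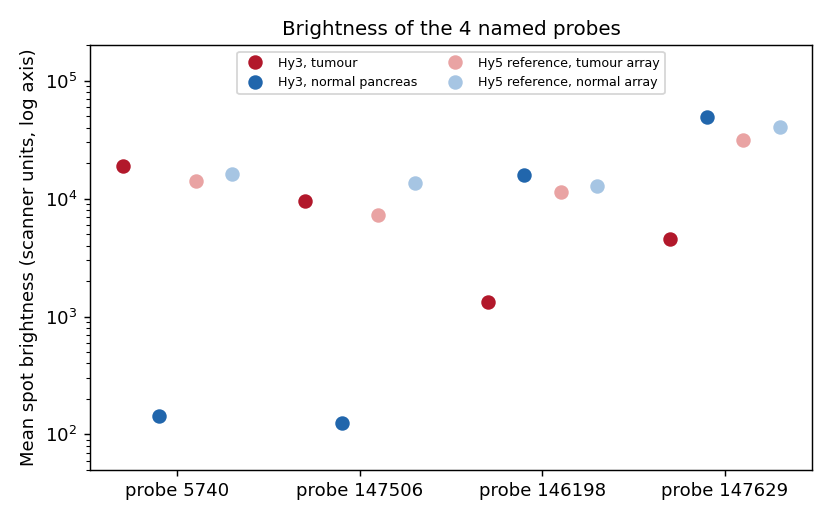
Mean spot brightness (scanner units, log axis) of the 2 probes with the highest and the 2 with the lowest tumour minus normal difference, in Hy3 (tissue) and Hy5 (blended reference) on each array. Each point is the mean of 4 spots on 1 array, and the Hy3 points are far apart (18762 against 144 for probe 5740) while the Hy5 points lie closer together.

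Over the probes, the differences between the tissues were spread more widely than the spots of a probe and than the reference channel's differences. The median SD between spots of a probe was 0.07 on the tumour array and 0.09 on the normal array. The Hy5 channel carried the same reference on both arrays and so should not differ between them. After loess and Aquantile, its difference had an SD of 0.16 over the 2516 probes, against 0.69 for the difference between the tissues. With median centring or without within-array normalization the SD of the reference difference was 0.29, more than 1.5 times as large. The central 95% of probes lay between -0.44 and 0.23 in the reference and between -1.05 and 1.72 in the tissue comparison. Only 5 probes differed by at least 2-fold in the reference channel. Among bright probes the SDs were 0.32 and 1.52. The measures are not alike, since the reference value is from Hy5 alone after a step between arrays. The tissue value is from log ratios without that step. Of 2653 probes 1320 passed the flag in Hy5 on both arrays, so many reference differences rest on dim signal. Variation between animals is not part of this yardstick. Nor is the choice of normalization, which moved the median difference of the bright probes from 0.07 to 1.29.

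Some probes passed the scanner flag in 1 tissue only, 21 in the tumour and 38 in normal pancreas. When every kept spot had to pass it, these numbers were 30 and 62. The planned bounds on their folds were at most 1.97 for the tumour and 1.35 for normal pancreas, with 0 at 2-fold or more. Of the 21 and the 38 probes 0 exceeded the level of the dim repeated features, so these bounds are not read further. Of the 2516 probes that passed the flag in both tissues, 291 exceeded that level in the tumour only and 15 in normal pancreas only. A further 78 probes did not pass the flag in either tissue.

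The log ratios of the 2 arrays were set against each other, since a reference blended from the samples ties them together. Over the 2516 probes Pearson's r was -0.16 and Spearman's rho was 0.20, and over the 395 bright probes r was -0.69 and rho was -0.80. Without normalization r was 0.42 over all probes and -0.61 over bright probes. These are correlations across probes, which are not independent replicates. The direction of the ratios rests on the dyes stated in the labelling protocol, and opposed log ratios are possible for 2 tissues read against their own blend.

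**Figure D3:**
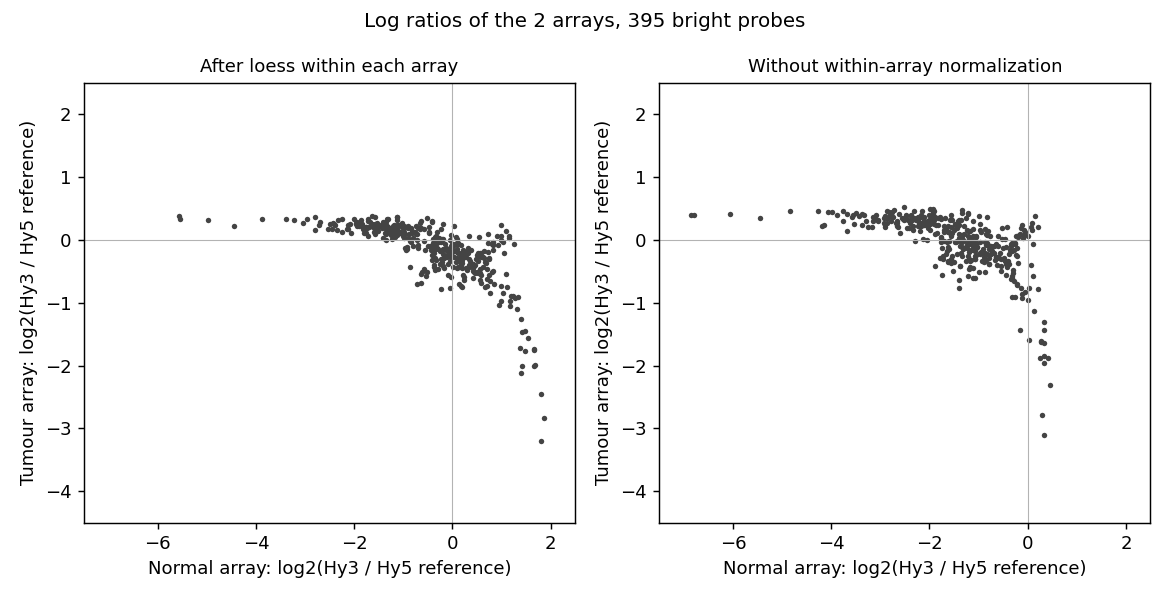
Log2(Hy3/Hy5) on the tumour array (vertical axis) against that on the normal array (horizontal axis) for the 395 bright probes, after loess and without within-array normalization, with 1 point per probe. The correlation was -0.69 after loess and -0.61 without it, and the points follow a bent line along which a low value on one array goes with a narrow range of high values on the other.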

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

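The test of the spots without a probe ID against the dim repeated features was chosen only after the result was seen. Signal was present in these spots, which the comparison of the tissues does not use. Of the 104 spots that share the placeholder ID -1, 66 on the tumour array and 52 on the normal array were brighter in Hy3 than every spot of the 4 dim repeated features, whose highest values were 165 and 186. After loess 33 of these spots were at least 2-fold higher in the tumour and 9 were at least 2-fold lower, and without normalization the counts were 44 and 2. Which probes they hold is not known here.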

How the results depend on the processing

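The equal-blend anchor, the mean level of at least 8, the floor of the dim repeated features and equal loess weights were tests chosen only after the result was seen. The 4 named probes kept their direction under each of 12 alternatives, with ranges of 5.92 to 7.37 for probe 5740, 5.16 to 7.30 for probe 147506, -5.01 to -3.30 for probe 146198 and -4.71 to -2.95 for probe 147629. They were picked as the most extreme probes and every alternative used the same spots, so the kept direction is no independent check. More probes were higher than lower under all of 20 alternatives but 1. The exception, after loess, required the floor of the dim repeated features to be exceeded on both arrays and gave 59 and 64. This filter removes probes dim in either tissue, and without normalization it left 149 and 14. Of the 2516 probes, 291 exceeded that floor on the tumour array only and 15 on the normal array only. Higher and lower probes numbered 300 and 137 from the scanner software's processed signals, 310 and 128 from the deposited value table by size alone, 307 and 20 with median centring, 371 and 18 with no within-array normalization, and 426 and 18 with the equal-blend anchor. They were 291 and 179 at 1.5-fold and 43 and 25 at 4-fold, as those thresholds dictate. Normexp with offset 10 gave 109 lower probes. The median difference was 0.15 with no normalization, 0.28 with the anchor and -0.28 with loess on spots above background in both channels. With median centring and with no normalization the correlation of the log ratios turned to 0.42 and the SD of the reference difference was 0.29. The correlation was -0.69 at a mean level of at least 8. Requiring every kept spot to be above background gave 62 probes in normal pancreas only. The other filters on dim probes, spot medians, no background subtraction and loess weights, all with loess, left both counts within 1.5 times. So did Hy3 alone after a step between arrays. None of these leaves normalization out. Apart from the thresholds, and from the tests of normalization among the other observations, the cause was not tested. No paired analysis was possible with 1 array per group, no replicate could be left out and slide could not be a block. The list medians, the planned set of mouse-named probes and the random lists were not run, since the probes carry no names. Probes of all species were used. With median Hy3 spots at 107 and 102 over a background of 24, signal over background limits the folds of dim probes.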

Other observations

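The tests of the highest log ratios before and after loess, of the SD of the summed ratios, of the equal-blend anchor and of the probes apart from the relation were chosen only after the result was seen.

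Without normalization, the higher of the 2 log ratios stopped at about the same value on both arrays. Its median was 0.33 on the tumour array in 129 bright probes at least 2 higher there on the log2 scale, and 0.32 on the normal array in 7 bright probes at least 2 lower in the tumour. An equal blend of 2 samples would cap the ratios in this way, because the 2 linear ratios must then add up to a constant. The median log2 of that sum was 0.63 in 72 bright probes that differed by under 0.5 and 0.51 in 136 that differed by at least 2, a gap of 0.11, which is consistent with a reference made of these 2 samples. Its SD over bright probes was 0.19, a low value that goes against a large share of another makeup. It cannot exclude a small share, since no such blend was simulated. The distance between the highest and the unchanged log ratios was 0.75, which missed the bound set beforehand for further samples in equal amounts. A condition on the SD, not part of that bound, was then applied and left the outcome undecided. The bound set for that distance assumed further samples unlike these 2, and more tumour and normal tissue of the same makeup would leave the sum constant.

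Without normalization, 89.9% of the bright probes were higher in the tumour, with a median difference of 1.29, and loess removed most of that shift by lifting the bright probes of the normal array by a median of 1.01. A brighter Hy3 channel on the tumour array would raise its highest log ratios as well, but these differed from the normal array's by 0.0074. The Hy5 difference of -0.37 between the arrays is too small to account for the whole shift. After loess, the normal array's highest log ratios lay 1.16 above the tumour array's, which an equal blend does not allow. That gap largely restates the loess shifts of the bright probes (medians of 1.01 on the normal and -0.13 on the tumour array). It is therefore no separate test, and loess fitted through changed probes stays a candidate source of the fewer higher and more numerous lower probes. What stays open is why the bright probes were lower in normal pancreas: a lower miRNA content per amount of total RNA, poorer RNA and a chance difference between 2 animals were not tested, and the reading rests on the labels' statement of equal amounts.

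As a hypothesis on the same data, shifting the normal array by 1 constant of -0.12, so that both sets of highest probes share 1 sum, gives a median difference of 1.42 in the bright probes. With this equal-blend anchor 253 bright probes were at least 2-fold higher and 15 were at least 2-fold lower in the tumour. Over all probes that passed the scanner flag the counts were 426 and 18, against 168 and 72 after loess. The lists of higher and of lower probes thus both depend on the normalization. Of the probes counted after loess, 167 of 168 higher and 18 of 72 lower ones were also counted without normalization. Of those counted without normalization, 167 of 371 higher and all 18 lower ones were also counted after loess.

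A set of 16 bright probes stood apart from this relation, with summed ratios more than 0.4 above the median on the log2 scale. They were chosen for that sum. Without normalization their log ratios had medians of 0.14 on the tumour array and -0.07 on the normal array, and their differences ran from -0.18 to 0.36. The brightest repeated feature, spotted 180 times, had a median Hy3 brightness of 12528 on the tumour array and 12543 on the normal array. Its median Hy5 brightness was 61 and 62, near the local Hy5 backgrounds of 58 and 60. It thus carried almost no reference signal. A reference blended from these tissues, as the labels state, would carry their RNA as well. These values therefore argue against tissue RNA as the source of this feature's Hy3 signal.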
